A study of Mus musculus with 8 samples.

How the data were processed

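RNA was sequenced from naive CD4 T cells sorted from lymph nodes of C57BL/6 mice and activated in culture for 20 h. The 8 libraries comprise 4 control cultures and 4 cultures with added iron, which the labels call FAC. Each mouse number in the labels names 1 control and 1 FAC culture, so a library is identified here by its group and mouse. Per the labels' protocols, 250 ng of total RNA per library entered a stranded mRNA library kit, so antisense genes can be told apart only if the counting used strand, and that setting is not given in the sources used here.

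The submitters' processing notes name FastQC, STAR 2.7.6a, RSEM 1.3.1, R 3.6.3, DESeq, DESeq2 1.26.0 and the genome build GRCm39, with no role or order. The annotation release is not given in the sources used here. Per the file headers, the authors deposited gene-level RSEM output for each library. The expected counts deposited by the authors are estimated read counts per gene, not scaled between libraries, and 88.6% to 89.4% of genes per library held a value within 0.005 of a whole number. The same deposited files hold TPM values, which the authors' RSEM run scaled for transcript length and to a fixed total in each library. They also hold an effective gene length in bases, which served only as an offset. A single deposited table gives a normalised signal for 13751 of the 57010 genes. In it the authors scaled gene counts between libraries with factors that differ from gene to gene, and every gene kept has a mean above 5, the smallest being 5.06; how the scaling and the gene filter were set is not given in the sources used here. In control 1, the ratio of that table to the expected counts ran from 1.07 at the 5th to 1.31 at the 95th percentile of genes with at least 50 counts.

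Library totals ran from 25410267 to 37350609 counts. At these totals 1 count equals 0.0272 to 0.0396 CPM, and 3 counts, taken as the floor for a count of 0, equal 0.0816 to 0.119 CPM. Reads carry no molecular identifiers, so these limits cover counting error only. Replicates of a group differed by more than sampling noise, so each library was counted as 1 replicate.

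Gene symbols came from the deposited table and, for other genes, from GENCODE M21, an annotation of the earlier build GRCm38. No coordinates are printed for that reason. The annotation was used for symbols, gene types, GC content, length and the order of neighbouring genes. It also gave the position and strand of non-coding transcripts relative to expressed genes, which are thus those of the earlier build. A symbol was found for 52034 gene identifiers, and GC content for 13158 of the 13378 tested genes (98.4%).

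The test of every gene was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on expected counts rounded to whole numbers. Low counts were removed with edgeR's expression filter (minimum count 10, minimum total 15), which kept 13378 genes holding 99.9% of all counts. Factors between libraries were TMM factors, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each adjusted p called "edgeR adjusted p" is from this test, and CPM values, counts scaled to a common library total, are on the TMM scale. The SE of a gene's log2 change is the absolute change over the square root of the test's F statistic. It is thus approximate, above all at low counts. The fit used the group alone and did not model the pairing of cultures by mouse, also where 1 library was left out. The mouse as a replicate block was an alternative, because a mouse number marks cultures of the same animal. Deviations of each library from its group mean were correlated across the 13378 tested genes. Between the libraries of a mouse, r was 0.137, 0.0165, 0.0647 and 0.139 for mice 1 to 4. The highest r between libraries of different mice was 0.0331, above that of mouse 2. The mean r between different mice, -0.0298, is set largely by centring each group on its mean. Genes are not independent replicates, and the pairing rests on the mouse numbers, not on these correlations.

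Gene lists were fixed before the data were examined: 44 lists cover iron handling, iron-dependent enzymes, T cell programmes, metabolism, stress responses and markers of other cell types. Of 904 listed symbols, 887 matched a gene. The 36 lists with at least 3 tested members were tested with camera on voom values (limma 3.58.1), at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists; this is the "camera adjusted p". Each list is also counted by its called genes over all genes tested, and by calls adjusted over the list alone. Shares of mitochondrial, ribosomal protein, histone, haemoglobin and immunoglobulin genes, totals and genes detected were compared with two-sided exact permutation tests over the 70 assignments of the libraries; the smallest p these can give is 0.0286. The shares of non-coding genes and of the top 100 genes were added after the data had been seen.

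Genes named in the text follow a rule set before the data were examined. It takes the 12 largest rises and the 12 largest falls among called genes with a mean log2 CPM of at least 1, an established symbol and the same direction in all 4 mice. It adds from each list up to 4 tested members with the smallest p, and 13 genes fixed in advance: Tfrc, Fth1, Ftl1, Slc40a1, Tbx21, Ifng, Il2, Il2ra, Cd69, Pdcd1, Hif1a, Myc and Cd4. The rule gave 160 genes, of which 159 were tested; any other gene is said to have been chosen after its values were seen. Some genes that the rule takes are not reported here, and the search for libraries apart from their group left out those same genes; others are only counted with their lists.

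Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library totals, other count filters, limma on log2(TPM + 1) and log2(TPM + 0.1), limma on the log2 deposited signal with pseudocounts of 1 and 0.5, a GC and length correction, the replicate block, and leaving out each library or mouse in turn. For the lists they were camera with an estimated correlation, camera on ranks and fry, limma's rotation test of a list on its own. An offset for effective gene length was added after the data had been seen. The fits were also tested on simulated data: counts drawn for the 13378 tested genes at the means of these libraries, with 50 genes changed at each fold. For FAC against control, the edgeR fit recovered 46% of genes changed 1.25-fold, 66% at 1.5-fold, 82% at 2-fold and 96% at 4-fold, with 14 false among 159 calls. The simulated counts held no effect of the mouse, so they cannot weigh the fit on the group alone against the replicate block.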

Results

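Gene expression was measured by RNA sequencing in mouse CD4 T cells, sorted in the naive state and activated for 20 h on plates coated with antibodies to CD3 and CD28 (4 µg/mL each). These engage the T cell receptor and its costimulatory receptor. Cells of 4 mice were each cultured without and with added iron, giving 4 control and 4 FAC libraries. The design asks how iron acts on T cell responses; the labels state neither the dose nor whether the control cultures received a vehicle. Total counts were 25478716, 37350609, 30464577 and 28509023 for control mice 1 to 4 and 31428728, 32368377, 28700514 and 25410267 for FAC mice 1 to 4. They were higher with FAC in 1 of 4 mice and the difference between groups did not pass a two-sided exact permutation test (p = 0.83).

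With FAC, 7 of 24 type 1 helper genes, 14 of 31 interferon gamma response genes and the transferrin receptor gene were lower, and 23 of 25 cholesterol synthesis genes were higher. With an estimated correlation, camera called the last of these lists (adjusted p = 0.00815, but 0.0783 with the replicate block as well) and neither of the first 2 (adjusted p = 0.107 and 0.120). Among called genes with a mean log2 CPM of at least 1, an established symbol and the same direction in all 4 mice, the largest falls were in Tbx21, Irf1, Gbp6, Tgtp2 and Gbp2. The largest rises in that set were in Fosb, Lipg, Cacnb3, D7Bwg0826e and Lpin1. Lipg, which encodes endothelial lipase, rose from 2.01 ± 0.523 to 4.84 ± 0.394 CPM (log2 change 1.27, SE 0.18, edgeR adjusted p = 0.00202). Lpin1, which encodes a phosphatidate phosphatase, rose from 3.55 ± 0.275 to 6.91 ± 0.83 CPM (0.96, SE 0.13, edgeR adjusted p = 0.00100). Crabp2, which encodes a retinoic acid-binding protein, fell by 1.06 on the log2 scale (SE 0.08, edgeR adjusted p = 6.75e-06), and Zbtb32, which encodes a zinc finger repressor, fell by 0.86 (SE 0.06, edgeR adjusted p = 1.05e-06). Each of these 4 genes moved the same way in 4 of 4 mice. The immediate early genes Fosb (1.96, SE 0.43, edgeR adjusted p = 0.0256) and Jun (0.88, SE 0.18, edgeR adjusted p = 0.0194) were also higher. Their calls ended without control 1, 2 or 3 or FAC 2 or 3, where the edgeR adjusted p reached 0.0929 for Fosb and 0.0811 for Jun without FAC 2. All libraries with the replicate block gave 9.63e-06 for Fosb and 1.86e-05 for Jun. Casz1 and Rnf225 (0.95 and 0.84, edgeR adjusted p = 0.0256 and 0.0425) were also in that set. The Casz1 call ended without control 1, 2 or 4 or FAC 2 or 3 (0.0946 without FAC 2). The Rnf225 call ended without control 1, 2 or 3 or FAC 2, 3 or 4 (0.159 without FAC 3).

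In all, 438 of 13378 tested genes changed at an edgeR adjusted p under 0.05, 291 higher and 147 lower with FAC, and 2463 had an unadjusted p under 0.05. Of the 438, 122 changed by at least 1.5-fold and 48 by at least 2-fold, 32 higher and 16 lower. With the replicate block the count was 919 (544 higher, 375 lower), which included 436 of the 438. It was 601, 454, 165 and 1217 without mouse 1, 2, 3 and 4. In the fit on the group alone, the count was 188, 209, 247 and 342 without control 1, 2, 3 and 4. It was 549, 168, 147 and 549 without FAC 1, 2, 3 and 4. Of the calls, 66.4% were higher with FAC, against 77.8% with limma on log2(TPM + 1) and 49.5% with the replicate block and a GC and length correction. Of 80 named genes called, 47 were called in each of the 8 fits that left out a library. Of the 80, 35 were no longer called in limma on log2(TPM + 1) and 33 in limma on the log2 deposited signal, and 0 turned direction. Both settings ended, among others, the calls of Nr4a3, Pfkl, Ak4, Slc30a1, Ifi209 and Itgb1. Of 36 gene lists tested, camera called 15, 2 higher and 13 lower, at its preset correlation, against 1 with an estimated correlation; other groupings of the same libraries gave up to 14 lists at the preset correlation. By gene type, 230 protein-coding genes were higher and 139 lower, whereas of 1133 tested non-coding or unclassified transcripts 50 were higher and 1 was lower (median log2 change 0.28, and 0.28, 0.31, 0.38 and 0.06 in mice 1 to 4). The median was 0.51 for those wholly inside, or within 5 kb after, an expressed protein-coding gene on the same strand, and 0.22 for the others. Summed counts of olfactory and vomeronasal receptor genes were also higher with FAC in 4 of 4 mice (mean log2 change 0.35, SE 0.0755).

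**Figure D1:**
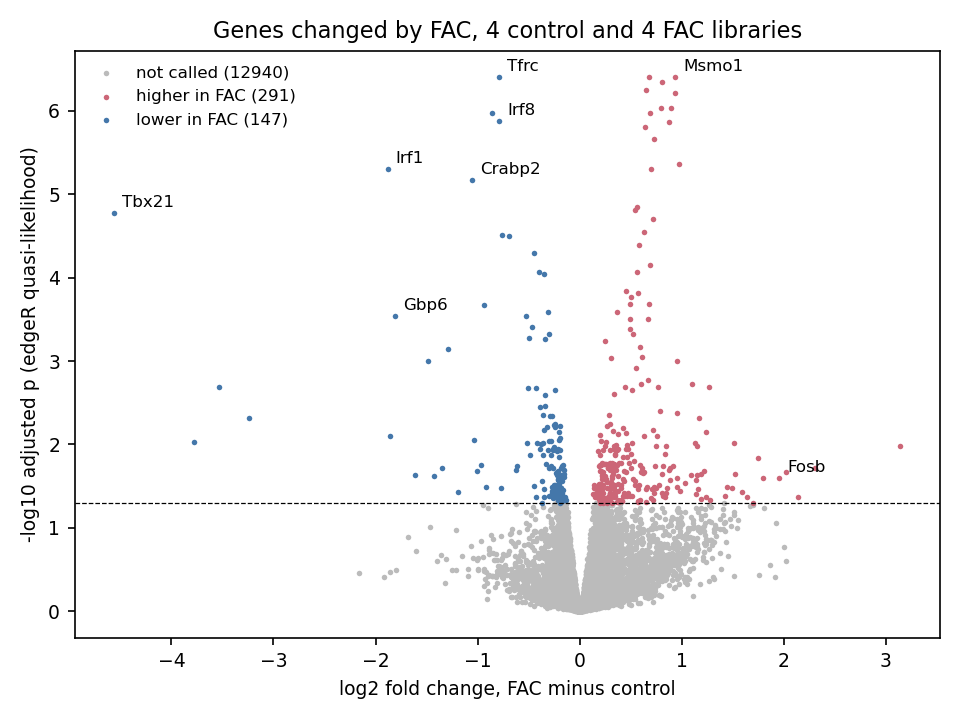
Each point is 1 of 13378 tested genes; the x axis is the log2 fold change (FAC minus control) and the y axis is -log10 of the edgeR adjusted p, with a dashed line at 0.05. The 291 genes higher with FAC are red, the 147 lower genes blue and the others grey; Tbx21 lies farthest to the left at -4.56.

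The type 1 helper list and the interferon gamma response list were lower with FAC at camera's preset correlation (adjusted p = 0.107 and 0.120 with an estimated correlation). The series title speaks of a boost to type 1 responses by iron, whereas these lists were lower in the libraries labelled FAC. The lists here are RNA of naive CD4 T cells activated for 20 h, and the title may rest on other cells, times or measures. Tfrc, whose transcript is degraded when cells hold ample iron, was lower in the libraries labelled FAC in 4 of 4 mice (-0.79, edgeR adjusted p = 3.97e-07). Tbx21 (ENSMUSG00000001444), which encodes T-bet, the transcription factor that directs type 1 helper differentiation, fell from 4.22 ± 1.48 to 0.168 ± 0.115 CPM (log2 change -4.56, SE 0.40, edgeR adjusted p = 1.67e-05). The counts behind it were 72, 204, 92 and 155 in the control libraries of mice 1 to 4 and 8, 9, 3 and 1 in the FAC libraries. Irf1 (ENSMUSG00000018899), an interferon-induced transcription factor, fell from 47.1 ± 10.9 to 12.8 ± 1.67 CPM (-1.88, SE 0.15, edgeR adjusted p = 4.99e-06).

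The median log2 change of 31 tested interferon gamma response genes was -0.35 (camera adjusted p = 8.13e-19, and adjusted p = 0.120 with an estimated correlation). Of these, 14 fell and 17 did not pass the test (21 lower when adjusted over the list alone, and 18 with the replicate block). They included the guanylate-binding protein genes Gbp6 (-1.81, SE 0.21) and Gbp2 (-1.29, SE 0.17) and the immunity-related GTPase genes Tgtp2 (-1.48, SE 0.20) and Igtp (-0.93, SE 0.11), with edgeR adjusted p of 2.88e-04, 7.13e-04, 0.00100 and 2.10e-04. Several members of these families, such as Tgtp1 and Tgtp2, have near-identical copies, so how reads were divided between copies is uncertain. The median of 24 tested type 1 helper genes was -0.26 (camera adjusted p = 5.26e-07, and adjusted p = 0.107 with an estimated correlation). Of these, 7 fell (9 when adjusted over the list alone, and 9 with the replicate block). Irf1 stands in both lists. The chemokine genes Ccl4 and Ccl3 fell by 0.45 and 0.39, and the lymphotoxin gene Lta by 0.50 (SE 0.04, 0.06 and 0.06; edgeR adjusted p = 5.05e-05, 0.00356 and 5.23e-04). Ifng itself was near 1 CPM in both groups and did not pass (1.03 ± 0.187 and 0.775 ± 0.0651 CPM, log2 change -0.41, SE 0.26, edgeR adjusted p = 0.424). Il2 did not pass either (-0.33, SE 0.14, edgeR adjusted p = 0.240, against 5.69e-04 with the replicate block). Of 27 type I interferon genes, Ifi209 rose (0.79, SE 0.12, edgeR adjusted p = 0.00399) and Ly6a and Parp14 fell (-0.96 and -0.30; edgeR adjusted p = 0.0179 and 0.0192). The list was not called (3 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.396). The Ly6a call ended without control 2 or FAC 2 (0.0622 without control 2) and the Parp14 call without control 1 or FAC 3 (0.0765 without FAC 3).

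Genes of sterol synthesis rose together. Of 25 tested cholesterol synthesis genes, 23 rose and the other 2 did not pass (23 also when adjusted over the list alone). The median log2 change was 0.68 and the range 0.07 to 0.94. The list was called by camera (camera adjusted p = 3.90e-53, and adjusted p = 0.00815 with an estimated correlation). With the replicate block as well, adjusted p = 0.0783 with an estimated correlation. Hmgcs1 (ENSMUSG00000093930), which encodes an early enzyme of the mevalonate pathway, rose from 145 ± 6.46 to 278 ± 24.1 CPM (0.94, SE 0.06, edgeR adjusted p = 6.10e-07). Msmo1, Fdps, Insig1 and Cyp51 rose by 0.94, 0.89, 0.80 and 0.68. Each of these 5 genes was higher in 4 of 4 mice and called in every fit that left out a library.

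Of 15 tested fatty acid synthesis genes, 8 rose (9 when adjusted over the list alone; median 0.20; camera adjusted p = 1.03e-09, and adjusted p = 0.0849 with an estimated correlation). Elovl6, a fatty acid elongase gene, rose by 0.56 (SE 0.06, edgeR adjusted p = 8.46e-05) and Fasn, the fatty acid synthase gene, by 0.27 (SE 0.04, edgeR adjusted p = 0.00596). The desaturase gene Fads2 rose by 1.51 (SE 0.27, edgeR adjusted p = 0.00949), from 0.699 ± 0.232 to 2.00 ± 0.297 CPM. Of 17 fatty acid oxidation genes edgeR called 0 (0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom; camera adjusted p = 0.861).

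**Figure D2:**
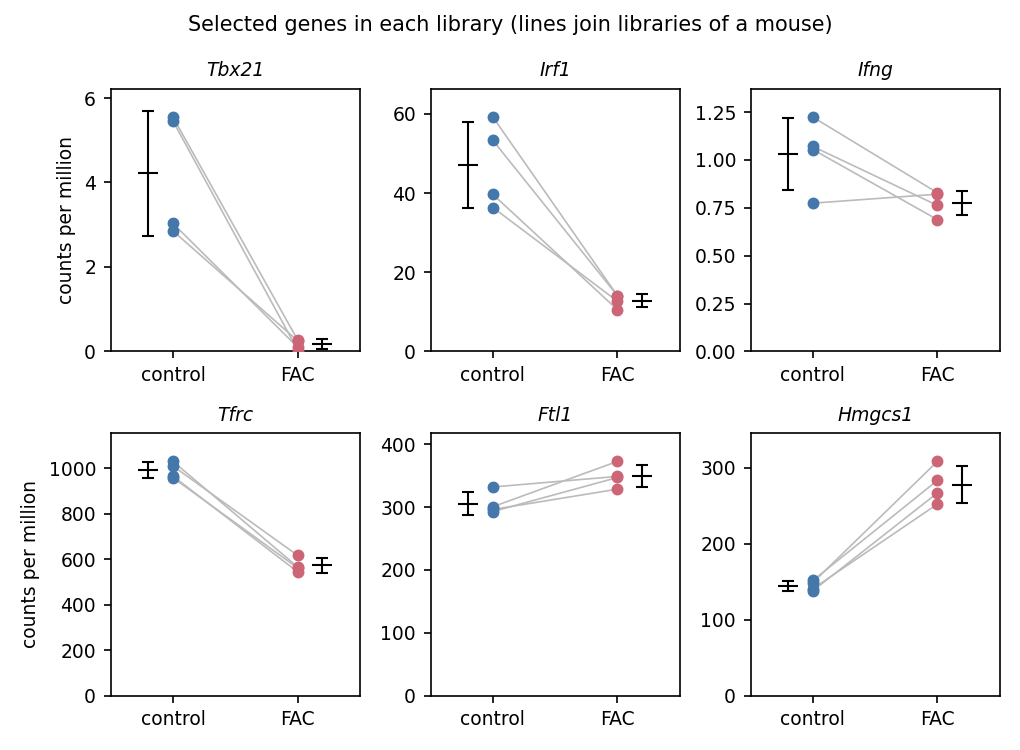
TMM-scaled CPM of 6 genes in each library, with grey lines joining the control and FAC cultures of a mouse and black marks giving the mean ± SD (n = 4 per group). Tbx21, Irf1 and Tfrc were lower and Hmgcs1 higher with FAC in every mouse, while Ifng was lower in 3 of 4 mice and did not pass the test.

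Tfrc (ENSMUSG00000022797), the transferrin receptor gene, fell from 991 ± 34.6 to 572 ± 31.2 CPM (-0.79, SE 0.04, edgeR adjusted p = 3.97e-07). Of 27 tested iron handling genes it was the only one that fell, and 5 were slightly higher (2 lower and 5 higher when adjusted over the list alone). The list was not called (camera adjusted p = 0.387). The 5 were Ncoa4, the ferritin autophagy receptor gene (0.22), Mcoln1 (0.34), the mitochondrial iron carrier genes Slc25a28 (0.31) and Slc25a37 (0.24, higher in 3 of 4 mice, chosen after its values were seen), and Ftl1, a ferritin light chain gene with many pseudogene copies (0.19, SE 0.05). Their edgeR adjusted p were 0.0241, 0.0339, 0.0430, 0.0482 and 0.0449, in that order. The calls of Ncoa4, Mcoln1, Slc25a28 and Ftl1 each ended without control 3, FAC 2 or FAC 3, with edgeR adjusted p of up to 0.0813, 0.129, 0.154 and 0.152. They also ended without control 1 for the last 3, and without control 2 for the first 3. Further losses came without control 4 for Ncoa4 and Ftl1, without FAC 4 for Slc25a28 and Ftl1, and in limma on the log2 deposited signal for all 4. The Slc25a37 call ended without control 1, 2 or 3 or FAC 1, 2 or 3 (0.176 without FAC 3). Fth1, the ferritin heavy chain gene, did not pass (324 ± 23.0 and 340 ± 15.4 CPM; 0.07, SE 0.05, edgeR adjusted p = 0.525). The iron exporter gene Slc40a1 had 0 counts in all 8 libraries, which allows up to 0.0816 to 0.119 CPM in each.

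Among 31 genes of iron-sulphur cluster and haem synthesis, Mms19 was higher (0.23) and Cpox lower (-0.20), at edgeR adjusted p of 0.0499 and 0.0395 (camera adjusted p = 0.136 for the list, 0.0373 without FAC 4 and 0.0210 without a filter on low counts). Among 31 iron-dependent dioxygenase genes, Alkbh1 was higher (0.26) and Egln3 (-0.62), P4ha1 (-0.23) and Alkbh5 (-0.13) lower, at edgeR adjusted p of 0.0260, 0.0201, 0.0223 and 0.0462 (camera adjusted p = 0.578). Adjusted over the list alone, 2 genes were higher and 1 lower in the former list, and 2 higher and 4 lower in the latter. All 6 calls ended without FAC 2 or FAC 3, with edgeR adjusted p of up to 0.177 for Mms19, 0.122 for Cpox, 0.105 for Alkbh1, 0.0823 for Egln3, 0.0863 for P4ha1 and 0.156 for Alkbh5. Without control 1 those of all but Egln3 ended, without control 2 those of Mms19, Cpox, Egln3 and Alkbh5, and without control 3 those of all but P4ha1. Without control 4 those of Mms19, Cpox, Alkbh1 and Alkbh5 ended, without FAC 1 that of Mms19, and without FAC 4 those of Cpox and Alkbh5.

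T cell activation genes were lower as a group. Of 29 tested, 7 fell (11 when adjusted over the list alone; median -0.09; camera adjusted p = 2.49e-07, and adjusted p = 0.0849 with an estimated correlation). With the replicate block 12 fell and 1 rose. Irf8, an interferon-responsive transcription factor gene, fell by 0.79 (SE 0.05, edgeR adjusted p = 1.32e-06) and the orphan nuclear receptor gene Nr4a3 by 0.34 (SE 0.05, edgeR adjusted p = 0.00255). Cd40lg, the CD40 ligand gene, fell by 0.36 (SE 0.07, edgeR adjusted p = 0.0134, and 0.0533 without FAC 2). The activation markers Il2ra (-0.08, SE 0.04, edgeR adjusted p = 0.240) and Cd69 (0.16, SE 0.15, edgeR adjusted p = 0.612, against 0.0164 with the replicate block) did not pass. Myc did not pass either (-0.13, SE 0.04, edgeR adjusted p = 0.116, against 0.0270 with the replicate block). Among 11 tested inhibitory receptor genes 3 fell (3 when adjusted over the list alone; camera adjusted p = 0.0184, and adjusted p = 0.120 with an estimated correlation). The call of this list ended with camera on ranks (0.167). Pdcd1, which encodes PD-1, fell from 149 ± 2.16 to 120 ± 3.21 CPM (-0.31, SE 0.04, edgeR adjusted p = 2.58e-04). Lag3 fell from 83.6 ± 5.12 to 58.8 ± 6.85 CPM (-0.51, SE 0.07, edgeR adjusted p = 0.00209). The third, Cd200, had an edgeR adjusted p of 0.0482, which rose above 0.05 without any library except FAC 1 (0.170 without FAC 3).

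Of 24 cytokine genes, 4 fell and 1 rose (7 and 1 when adjusted over the list alone; camera adjusted p = 5.02e-04, and adjusted p = 0.292 with an estimated correlation), and with the replicate block 8 fell and 1 rose. Lta, Ltb, Ccl3 and Ccl4 were lower. Il16, chosen after its values were seen, was higher (0.38, edgeR adjusted p = 0.0361; 0.132 without FAC 3, and not called without control 1, 2 or 4 or FAC 2 or 4). Of 18 interleukin 2 response genes 2 fell (5 when adjusted over the list alone; camera adjusted p = 0.00125, and adjusted p = 0.0849 with an estimated correlation), and 5 with the replicate block. Without the block these were the feedback inhibitor gene Cish (-0.40, SE 0.04, edgeR adjusted p = 8.46e-05) and Tnfrsf4, the OX40 gene (-0.14, edgeR adjusted p = 0.0422, not called without any library except FAC 1, 0.154 without FAC 3). NF-kB targets were not called as a list (camera adjusted p = 0.396). Of 24, Nfkbid, Lta, Ltb, Ccl3 and Ccl4 fell. Traf1, chosen after its values were seen, rose (0.21, edgeR adjusted p = 0.00907). Adjusted over the list alone, 6 were lower and 3 higher, and with the replicate block 6 were lower and 2 higher. In this list the median change was 0.02 and the mean -0.06.

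Lists of the other helper programmes had up to 3 called genes each. The Th17 list was lower (camera adjusted p = 0.00667, and adjusted p = 0.120 with an estimated correlation). Of its 8 genes, 1 fell (3 when adjusted over the list alone and 3 with the replicate block). The follicular helper list was lower (camera adjusted p = 0.0257, and adjusted p = 0.333 with an estimated correlation). It had Pdcd1 and Cd200 lower and Slamf6 higher (0.22, edgeR adjusted p = 0.0422) among 8 genes (3 lower and 1 higher when adjusted over the list alone, 4 lower and 1 higher with the replicate block). Its camera adjusted p was 0.108 on ranks, 0.0620 without FAC 2, 0.0504 without control 4 and 0.0658 without FAC 4. The Slamf6 call ended without control 1, 2 or 3 or FAC 1, 2 or 3 (0.160 without FAC 3). The type 2 helper list (7 tested; camera adjusted p = 0.231) and the regulatory T cell list (12 tested; camera adjusted p = 0.209) were not called, but were without a filter on low counts (0.0470 each). Each had 1 lower gene, Ccr8 (-0.33, edgeR adjusted p = 0.0172) and Tnfrsf4 (1 and 2 lower when adjusted over the list alone, and also with the replicate block). Of 24 naive T cell genes 2 rose (3 when adjusted over the list alone; list not called, camera adjusted p = 0.252). Satb1 was higher (0.18, edgeR adjusted p = 0.0425), and was not called without control 1, 2 or 4 or FAC 2 or 3 (0.162 without FAC 3). Of 17 chemokine and homing receptor genes, 1 was higher and Ccr8 and Itgb1 lower (4 higher and 2 lower when adjusted over the list alone, 3 and 2 with the replicate block; camera adjusted p = 0.984, median -0.03, mean 0.01). Cd4 did not pass (623 ± 11.8 and 606 ± 13.0 CPM; edgeR adjusted p = 0.559). The T cell identity list was not called (19 tested; camera adjusted p = 0.924), with 1 gene each way, also when adjusted over the list alone. Cd247, the CD3 zeta chain gene, was lower (-0.27, SE 0.04, edgeR adjusted p = 0.00453). Cd5 was higher (0.14, edgeR adjusted p = 0.0304, and 0.127 without FAC 3; not called either without FAC 2 or any control library).

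**Figure D3:**
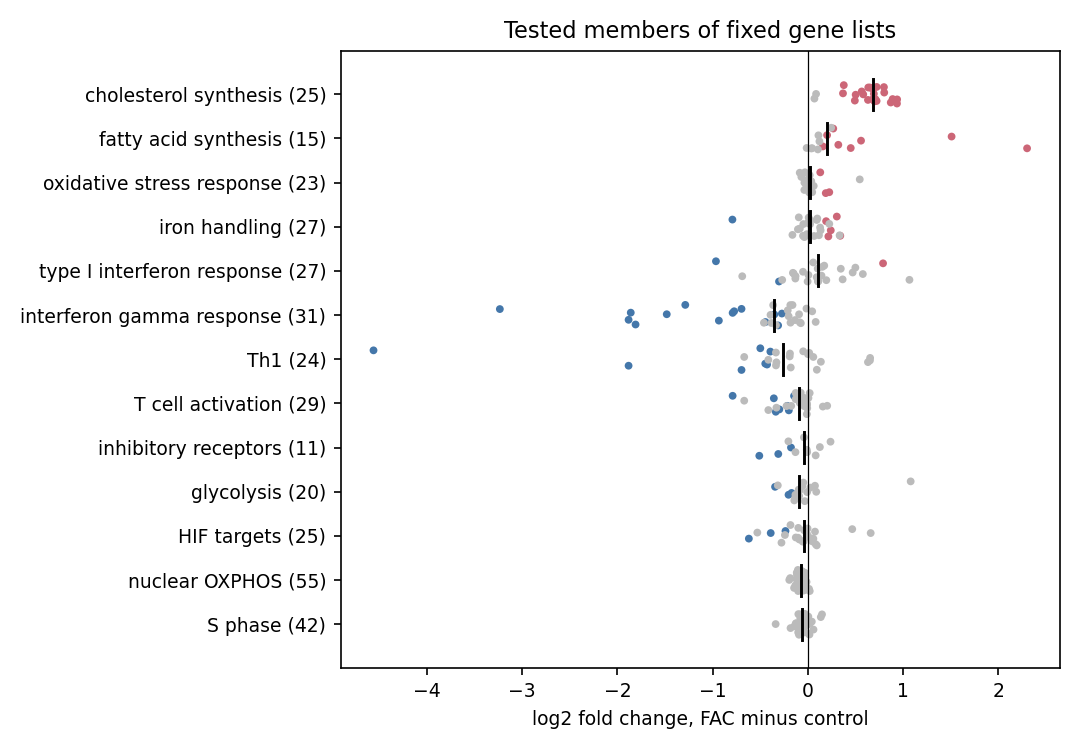
Log2 fold changes (FAC minus control, x axis) of the tested members of 13 gene lists, with the number tested in parentheses and a black bar at the median. Red points were higher and blue points lower at an edgeR adjusted p under 0.05, and grey points did not pass; 23 of 25 cholesterol synthesis genes are red and 14 of 31 interferon gamma response genes are blue.

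Glycolysis genes were lower as a group: 3 of 20 fell (8 when adjusted over the list alone, 7 with the replicate block; median -0.09; camera adjusted p = 3.40e-05, and adjusted p = 0.205 with an estimated correlation). Tpi1 fell by 0.34 (SE 0.05, edgeR adjusted p = 0.00348) and Pfkl by 0.20 (SE 0.03, edgeR adjusted p = 0.00716). The third, Pgam1, was lower at an edgeR adjusted p of 0.0182, and of 0.0924 without FAC 2, and was not called either without control 1, control 3 or FAC 3. Among 25 hypoxia-inducible genes, Ak4, Egln3 and P4ha1 were lower (5 lower when adjusted over the list alone; camera adjusted p = 0.0257, and adjusted p = 0.120 with an estimated correlation). The call of this list ended with the replicate block (0.0552), with camera on ranks (0.0812) and without control 3 (0.0552), FAC 1 (0.0710) or FAC 2 (0.0637). Hif1a did not pass (0.01, SE 0.04, edgeR adjusted p = 0.966).

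Lists of the respiratory chain, MYC targets and S phase were lower at camera's preset correlation (adjusted p = 0.385, 0.257 and 0.726 with an estimated correlation). In each, edgeR called 0 members, also when adjusted over the list alone. With the replicate block edgeR called Cycs lower (adjusted p = 0.0118) in the first, Myc and Npm1 lower (0.0270 and 0.0367) in the second and Pole higher (0.0353) in the third; Npm1 and Pole were chosen after their values were seen. Of 55 nuclear respiratory chain genes, 53 had a negative log2 change, with a median of -0.07 (camera adjusted p = 3.61e-08). Of these, 15 were lower at an unadjusted p under 0.05, 4 by DESeq2 and 0 by limma-voom. For 37 MYC target and ribosome biogenesis genes the median was -0.06 (camera adjusted p = 1.23e-04). In this list 9 were lower and 1 higher at an unadjusted p under 0.05, 1 was lower by DESeq2 and 0 changed by limma-voom. For 42 S phase genes it was -0.06 (camera adjusted p = 0.0121). Here 1 was higher and 1 lower at an unadjusted p under 0.05, and 0 changed by DESeq2 and limma-voom. The S phase call ended with a filter at 5 CPM (0.0612) and without control 2 (0.165), control 4 (0.494), FAC 1 (0.390) or FAC 3 (0.0969). Of 24 citrate cycle genes edgeR called 0 (1 lower at an unadjusted p under 0.05 and by DESeq2, 0 by limma-voom). The list was not called (camera adjusted p = 0.0511, but 0.0319 on ranks, 0.0474 with RLE factors, 8.55e-04 without a filter on low counts, 0.0362 without control 3, 0.0296 without control 4 and 0.00536 without FAC 4). Of 13 genes of the mitochondrial genome edgeR called 0 (3 higher and 1 lower at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom). With the replicate block mt-Cytb was higher and mt-Nd3 lower (adjusted p = 0.0367 and 0.0203). That list was not called (camera adjusted p = 0.252, but 0.0323 without control 2 and 1.26e-04 without FAC 4). Of 39 genes of G2 and M phase, Hjurp was higher (0.34, edgeR adjusted p = 0.0172, and 0.0743 without FAC 2; not called without control 1, 2 or 3 or FAC 3 either), also when adjusted over the list alone. The list itself was not called (camera adjusted p = 0.335, but 0.0111 without control 1 and 0.00536 without FAC 4).

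Lists of stress responses were not called. Chac1, a glutathione-degrading enzyme gene of the ferroptosis and integrated stress response lists, rose from 0.302 ± 0.0487 to 1.03 ± 0.334 CPM (1.74, SE 0.34, edgeR adjusted p = 0.0147; 0.0732 without FAC 3, and not called without control 1). Ppp1r15a, a phosphatase subunit gene of the integrated stress response, rose by 0.46 (SE 0.08, edgeR adjusted p = 0.00732). These were the 2 called genes of 32 in that list (camera adjusted p = 0.981). Chac1, Ncoa4 and Tfrc were those of 14 in the ferroptosis list (camera adjusted p = 0.396). The counts were the same when adjusted over the list alone, 2 higher in each and 1 lower in the latter. Both lists had a median change below 0 and a mean above it. Of 23 oxidative stress genes, Gclc, G6pdx and Txnrd1 were higher (0.23, 0.19 and 0.13; edgeR adjusted p = 0.0379, 0.0304 and 0.0395). Adjusted over the list alone 3 were higher (list camera adjusted p = 0.161, but 0.0396 without control 2). All 3 calls ended without control 1, control 4, FAC 2 or FAC 3 (up to 0.136, 0.110 and 0.144). Those of Gclc and Txnrd1 also ended without control 2, those of G6pdx and Txnrd1 without control 3 (0.116 for G6pdx) or FAC 4, and that of Gclc without FAC 1.

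Among 5 metal response genes the zinc importer gene Slc39a10 rose (0.50, SE 0.06, edgeR adjusted p = 2.08e-04). The zinc exporter gene Slc30a1 fell (-0.36, SE 0.07, edgeR adjusted p = 0.00975). Adjusted over the list alone 1 was higher and 1 lower (list camera adjusted p = 0.523). Of 24 p53 targets, Cdkn1a, a cell cycle inhibitor gene, fell (-0.53, SE 0.06, edgeR adjusted p = 2.88e-04). Sesn1 was higher (0.30, edgeR adjusted p = 0.0339, and 0.135 without FAC 3; not called without FAC 2 or any control library). Adjusted over the list alone, 3 p53 targets were lower and 1 higher, and with the replicate block 2 were lower and 2 higher. The list was not called (camera adjusted p = 0.0602, but 0.0141 without a filter on low counts, 0.0476 without control 1 and 0.0122 without FAC 2). Of 17 immediate early and heat shock genes, Fosb and Jun were the 2 called (3 higher and 1 lower when adjusted over the list alone, and also with the replicate block; camera adjusted p = 0.307, median -0.04, mean 0.14). Of 20 unfolded protein response genes edgeR called 0 (2 higher and 1 lower at an unadjusted p under 0.05; 0 by DESeq2 and limma-voom; camera adjusted p = 0.861, median -0.01, mean 0.0019).

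Markers of other cell types were low, and 8 such lists had fewer than 3 tested members. Summed over each list, control and FAC levels were 9.53 ± 1.20 and 7.95 ± 1.17 CPM for CD8 T cells. They were 2.73 ± 0.378 and 2.50 ± 0.526 for gamma delta T cells, 1.4 ± 0.547 and 1.44 ± 0.307 for NK cells. For B cells, almost all from Ighm, they were 98.2 ± 4.51 and 101 ± 6.72, and for myeloid and dendritic cells 42.0 ± 2.25 and 49.4 ± 3.52. The levels were 8.39 ± 0.755 and 9.49 ± 1.13 for stroma, 1.13 ± 2.01 and 0.0913 ± 0.106 for erythroid cells and 0.0164 ± 0.0328 and 0.0515 ± 0.0832 for granulocytes. The 1 called gene was Cd74 (0.35, edgeR adjusted p = 0.0418, and 0.134 without FAC 2; not called without control 1, 3 or 4 or FAC 3 or 4 either). Of the 7 planned measures of library composition 0 passed between groups, and two-sided exact permutation p ran from 0.171 for genes detected (18967 ± 379 and 19426 ± 379, higher with FAC in 4 of 4 mice) to 0.857. The share of counts in non-coding transcripts, examined after the data had been seen, was 0.775% ± 0.0142 in control and 0.888% ± 0.0656 in FAC libraries (SD, n = 4 each), higher with FAC in 4 of 4 mice. The exact permutation p was 0.0286, the smallest possible, and 0.257 adjusted over 9 measures. It was 0.0571 without any 1 of the control libraries.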

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

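The search for libraries apart from their group was planned. In 324 groups of 4 values, 1 library lay apart from the other 3 in 21, where chance gives 16.2. The measure is the gap to the nearest other library over the range of the group, against Dixon's 95% critical value. These gaps fell on every library, 2 each in controls 1 and 2, 3 in control 3, 4 in control 4, 2 each in FAC 1, 2 and 3 and 4 in FAC 4.

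Among FAC libraries, FAC 4 lay apart for Egln3 (5.87 CPM against 4.37 to 4.45, ratio 0.948) and Alkbh1 (56.2 against 64.8 to 66.3, ratio 0.852). It also lay apart for Pgam1 (573 against 532 to 535, ratio 0.933) and Gclc (53 against 57.5 to 58.3, ratio 0.850). FAC 2 lay apart for Cacnb3 (4.97 against 3.06 to 3.37, ratio 0.840) and Txnrd1 (312 against 321 to 322, ratio 0.885). FAC 3 lay apart for Satb1 (307 against 281 to 282, ratio 0.951) and Slc30a1 (13.1 against 13.7 to 13.9, ratio 0.860). FAC 1 lay apart for Pfkl (155 against 163, ratio 0.907) and Junb (155 against 181 to 184, ratio 0.906).

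Among control libraries, control 1 lay apart for P4ha1 (74.8 CPM against 65.8 to 67.2, ratio 0.842) and Mt1 (2.02 against 2.7 to 2.82, ratio 0.856). Control 2 lay apart for Ccl4 (150 against 135 to 137, ratio 0.872) and Hadhb (47.6 against 42.8 to 43.1, ratio 0.937). Control 4 lay apart for Ccr6 (2.32 against 1.59 to 1.69, ratio 0.864), Atf4 (319 against 336 to 337, ratio 0.945), as well as Lta (171 against 196 to 199, ratio 0.910) and Junb (186 against 199 to 202, ratio 0.848). Control 3 lay apart for Ccr8 (37.4 against 32.4 to 33.2, ratio 0.840), Hif1a (230 against 210 to 213, ratio 0.845) and the share of haemoglobin transcripts (4.20e-04% of counts against 0 to 1.05e-05%, ratio 0.975).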

How the results depend on the processing

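The effective length offset was chosen after the data had been seen; the other settings were planned. RLE or upper-quartile factors, library totals, filters at 1 or 5 CPM, limma-voom, leaving out mitochondrial genes and keeping protein-coding genes left all 3 gene counts within 1.5 times. The 438 changed genes (291 higher, 147 lower) became 744 (439, 305) with DESeq2, 697 with DESeq2 and the replicate block (352 lower), 736 (450, 286) without a filter on low counts, and 919 (544, 375) with the replicate block. They became 144 (112, 32) and 138 (108, 30) with limma on log2(TPM + 1) and log2(TPM + 0.1), and 156 (99, 57) and 147 (93, 54) with limma on the deposited signal at pseudocounts of 1 and 0.5. By construction they fell to 122 (95, 27) at 1.5-fold or more and to 114 (64, 50) at an adjusted p under 0.01. A GC and length correction gave 685 (294 lower) and, with the replicate block, 1231 (609, 622); the effective length offset gave 187 (126, 61) and, with the replicate block, 217 (143, 74). Library totals alone put 76.2% of calls higher, against 66.4%, and ended the calls of Cpox, Alkbh5, Tnfrsf4 and Cd200. Upper-quartile factors ended those of Alkbh5, Tnfrsf4, Cd200 and Ftl1. Leaving out 1 library, or 1 mouse with the replicate block, gave 147 to 1217 genes (80 to 734 higher, 65 to 483 lower). Of the 15 lists, 1 was called with an estimated correlation, 0 with an estimated correlation and the replicate block, and 31 of 36 lists with fry's mixed test. With fry's directional test 14 were called, which adds the ferroptosis list (0.0211) and ends the calls of the nuclear respiratory chain (0.0993) and S phase (0.679) lists. On ranks camera called 13, and leaving out a library gave 13 to 18. With the replicate block 21 more genes of the naming rule were called and 0 fewer, and with DESeq2 22 more. The block also changed the calls of Npm1, Pole, the hypoxia list and, with an estimated correlation, the cholesterol synthesis list (0.0783), and no other call of a named gene or of a list by camera. Deviations of libraries of a mouse correlated with a mean r of 0.316 over genes of at least 5 CPM, against 0.0895 over all tested genes. The cause was not tested for any of these shifts except where construction is named. Totals of 25410267 to 37350609 counts put 3 counts at 0.0816 to 0.119 CPM, which limits genes near 0.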

Other observations

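The tests of effector or NK cells and of overall activation, the spread used in the GC content and length tests, and Tbkbp1 were chosen after the results were seen. Below, the SE of a median or of a percentage of uncorrected size is from a bootstrap over genes, which does not measure spread between mice. The receptor gene SE is over the 4 mice. The permutation of non-coding transcripts by position also treats genes as units. Tbkbp1, the annotated neighbour of Tbx21, which encodes an adaptor that binds the kinase TBK1, was lower with FAC, at 1.70 ± 0.882 in control and 0.145 ± 0.0823 CPM in FAC libraries (SD, n = 4 each; log2 change -3.54, SE 0.51, edgeR adjusted p = 0.00203), and in 4 of 4 mice. It was called in each fit that left out a library, but not in limma on log2(TPM + 1) (adjusted p = 0.0649). The neighbours Sp6, Scrn2, Mrpl10, Osbpl7, Kpnb1, Npepps and Mrpl45 were not called, with edgeR adjusted p from 0.227 for Sp6 to 0.881 for Osbpl7.

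The counts of genes argue against chance without excluding it, since the 35 splits take no account of the mouse. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many changed genes (438, highest other 40), as many higher (291, highest other 34) and as many lower (147, highest other 34). The split with 40 genes set mice 1 and 3 against mice 2 and 4, and with the mouse as a replicate block the real contrast gave 919. Among the 8 splits that part all 4 pairs of libraries of a mouse, too few for a share under 0.05, the highest other gave 1 gene. The number of lists called at the preset correlation sets the real split apart by only 1 list (15, highest other 14, both among the 35 splits and among those 8), so it is weak evidence against chance.

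Tbx21 and 14 interferon gamma response genes were lower with FAC, with by-mouse medians of -0.66, -1.23, -0.67 and -1.04 for the 14. With a GC content and length correction and the replicate block their median was -0.85, or 99.3% of its uncorrected size (SE 1.53), with 14 called before and after, which argues against that bias. Of 11 transcripts of type 1 effector and NK cells, 8 were tested, with a median of -0.023 (SE 0.11). The 11 did not include Ccl3, Ccl4 and Lta of the fixed type 1 helper list, which were lower with FAC. In that list 7 of 24 genes were lower and 0 higher, with a median of -0.26. Among the 8 tested, the 3 with a mean log2 CPM above 1 were Nkg7 (-0.33, edgeR adjusted p = 0.132), Cxcr3 (-0.18, 0.579) and Gzmb (0.00242, 0.998). The others of the 8 were too low to weigh. The values of these 3 genes argue against a loss of such cells as large as the fall of the 14. They are few, and a smaller loss stays open. The activation list without Irf8 and Ifng (27 genes) had a median of -0.084 (SE 0.04) against -0.86 for the 14, which were picked as called, and -0.35 for all 31 genes of their list, which argues against an equal fall of all activation genes. The fall goes with FAC treatment of cells of the same mice, but how FAC would bring about this pattern was not tested. A smaller loss of type 1 effector or NK cells, or a smaller fall in activation, was not excluded as part of it. Iron and the rest of the compound cannot be separated, since the labels name no vehicle.

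The cholesterol synthesis list was higher with FAC in every mouse, with medians of 0.68, 0.62, 0.70 and 0.66. With the GC content and length correction and the replicate block the median was 0.68 (99.2% of its uncorrected size, SE 2.01), and 23 genes were called before and after. Over library totals, RLE and upper-quartile factors the lowest median was 0.68. TMM factors ran only from 0.985 to 1.01, so changing the factors could move the median only slightly. That comparison shows that the choice of factor did not make the rise, and no more. The GC content and length values argue against that bias as the whole cause. The rise goes with FAC treatment of cells of the same mice, but how FAC would bring it about was not tested. Only these technical sources were weighed, and iron and the rest of the compound cannot be separated here either.

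Non-coding and unclassified transcripts were mostly higher with FAC (1133 tested, 75.8% positive, by-mouse medians 0.28, 0.31, 0.38 and 0.06). The GC content and length correction left a median of 0.30 (108% of the uncorrected size, SE 2.10; 76 called before, 98 after), which argues against that bias. Genomic DNA carry-over stays open. Summed counts of olfactory and vomeronasal receptor genes were higher in 4 of 4 mice, as carry-over would give (mean log2 change 0.35, SE 0.0755). In mice 1 to 4 the receptor changes were 0.58, 0.30, 0.29 and 0.24. They were highest in mouse 1, whereas the non-coding median was highest in mouse 3, and both were lowest in mouse 4. Pseudogenes did not rise as a class (926 tested, 5 higher and 4 lower, median -0.04, 41.5% positive). Their values were not set as a test of carry-over. Unspliced RNA of expressed genes also stays open. The 290 transcripts wholly inside an expressed protein-coding gene on its strand, or within 5 kb after it, had a median of 0.51. The 843 others had a median of 0.22, a difference of 0.29 (permutation p = 1e-05, the smallest that 100000 permutations can give). Of these others, 72.5% were positive too. Antisense and partly overlapping transcripts count among them, so not all need lie away from expressed genes. A biological change stays untested, and the share of these transcripts had a permutation p of 0.0857 when taken from TPM values and 0.0571 without any 1 of the control libraries.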
